A study of Caenorhabditis elegans with 7 samples.

How the data were processed

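Small RNAs of 18 to 30 nt were sequenced from whole young adult Caenorhabditis elegans grown at 20 °C. Per the labels' protocols, total RNA was treated with tobacco acid pyrophosphatase before adapter ligation, so that small RNAs with a 5′ triphosphate could be cloned. The 7 libraries carry a set letter. Libraries of sets A and C had 5′ barcodes of 4 bases and those of set B had barcodes within TruSeq adapters. What the letters stand for beyond this is not given in the sources used here.

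Per the submitters' processing notes, reads were placed with Bowtie 0.12.7. Per the file headers, the genome build was ce6, with the sequence of the piRNA sensor or of the control sensor added for the 5 libraries that carry a transgene. Adapter trimming and mismatch settings are not given in the sources used here. Each deposited line is 1 placement of 1 distinct read sequence, with the number of reads of that sequence and its number of placements written into its name. The file headers call 4 libraries resampled (wild-type of set A, piRNA sensor in wild-type and in prg-1 of set B, and mut-7) and the other 3 reference. What the resampling did is not stated. The median number of reads per distinct sequence was 1 in both libraries of set A and in wild-type of set C, 4 to 5 in set B, and 3 in mut-7. Reads are therefore not independent molecules in every library, and every interval below covers counting error only.

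Each read was shared evenly over its placements. Classes were set by length, first base and place. The 22G class held reads of 21 to 23 nt that start with G, and the 26G class held reads of 26 nt that start with G. The 21U class held reads of 21 nt that start with T within 2 parts of chromosome IV of ce6, from 4.5 to 7 Mb and from 13 Mb to the end. Reads of miRNAs matched the first 19 nt of 1 of 90 mature sequences written down before the tests. Of these, 89 lay on the chromosome that the RefSeq gene table of WBcel235 gives for the miRNA and were used. Ribosomal DNA (rDNA) was the region of chromosome I from 15060001 to the end. Its sense strand was found to be the plus strand from reads with conserved rRNA sequence. Tc1 and Tc3 elements were located by their terminal inverted repeats, which gave 26 Tc1 elements of 1611 bp and 19 Tc3 elements of 2337 bp. Parts of the sensor were located by the reading frames of GFP, histone H2B and UNC-119 in the sequence spelled out by the reads.

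Only an annotation of WBcel235 was used here, for gene names and chromosomes. Because its coordinates differ from ce6, no read was assigned to a gene. In place of genes, the 22G class was counted by read 5′ end in 1 kb windows of each strand. Windows leave open which strand is antisense to a transcript, so the word antisense is used only for the sensor and for rDNA. Gene lists other than the 3 miRNA lists, and the genes prg-1, mut-7, bath-45 and xol-1, were not analysed here.

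The values are read numbers inside text names, deposited in part after resampling, so no count model was used. The design had foreseen one for tables of counts per gene. Instead limma 3.58.1 in R 4.3.3 was fitted to log2 of RPM (reads scaled to a library size of 1000000) plus a pseudocount of 1, for features with at least 1 RPM in at least 2 libraries. Folds on this scale understate changes of low features. The 5 libraries of sets A and B entered the fit, with set and genotype as terms and 2 residual degrees of freedom, and Benjamini-Hochberg adjusted p was held to 0.05. Library size was all deposited reads, or for 21U the reads outside that class. The labels do not say whether libraries of 1 genotype came from separate cultures, so p-values measure only the spread between these libraries. The spread of each feature was also moderated by limma towards that of the other features. Lists of miRNAs were tested with limma's camera, at a preset correlation of 0.01 and with an estimated one, and with fry.

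Set C holds 1 library of N2 and 1 of mut-7. No test was made there. A window was called lower or higher at a ratio of at least 4-fold with at least 50 reads in the higher library, in RPM relative to reads outside the sense strand of rDNA and the mitochondrial genome. The same scale was used for the sensor, with exact Poisson 95% intervals for single values and exact conditional binomial 95% intervals for ratios. Shares of reads have exact Clopper-Pearson 95% intervals. Where a library had 0 reads, a fold was computed against 3 counts in that library. Overlap of calls was tested with the hypergeometric distribution.

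Before the data were examined, a rule for named items was fixed for genes, and windows took the place of genes in it. Named 22G-class windows had the same direction in both sets and a mean of at least 10 RPM, and the 12 that fell most and the 10 that rose most were taken. For mut-7 these were the 12 lowest and 8 highest ratios with at least 200 reads in the higher library. For miRNAs they were the 5 with most reads, the 5 with the smallest adjusted p and up to 4 per list, and for 21U the 5 loci with most reads in the 4 N2 libraries. Tc1 and Tc3 were always included.

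Several choices were made only after the data were examined. These were the values of the filter on low features, rDNA sense and mitochondrial reads as a stand-in for structural RNA, and the bounds of the sensor parts. The outlines of Tc1, Tc3 and rDNA and the bounds of the second 21U region, at first set more narrowly, were also chosen then.

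The tests were tested on simulated data with the residual SD of each feature, from 2 residual degrees of freedom, and counting error drawn on top. That SD already holds counting error, so the simulated spread was wider than the fitted one. The numbers below therefore do not measure how many changes were missed in the data. The simulation was revised after its first results, at first to give each feature its own spread and then to add a round with a broad fall, and recovery stayed low. With 200 of 19457 windows changed 4-fold or 16-fold, none was called and no unchanged window was called. With 7783 windows lowered 4-fold, 10.2% of them were called, along with 16 of the 11674 unchanged windows. For 1257 loci of 21U, 8 of 100 changed 4-fold and 47 of 100 changed 16-fold were called, and 0 of 503 in a broad 4-fold fall. For 87 miRNAs, 5 of 10 changed 4-fold and 8 of 10 changed 16-fold were called, and 14 of 35 in a broad 4-fold fall. Of the unchanged, 1 of 1057 loci of 21U and 1 of 67 miRNAs were called. Beside a broad fall these numbers were 0 of 754 and 1 of 52. With even libraries and little spread, every changed feature was called. Alternatives covered the scaling, the filter, the set term, reads with several placements, the read class, the pseudocount, duplicated reads and the omission of each library. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for all other steps.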

Results

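The libraries compare wild-type worms (N2) with mutants of prg-1, which encodes the Piwi protein that binds piRNAs (21U-RNAs in this animal), and of mut-7, a gene needed to make secondary small RNAs of 22 nt that start with G (22G-RNAs). In 5 of the 7 libraries the worms also carried a transgene, the piRNA sensor or the control sensor. Set A held 1 library of N2 and 1 of prg-1, with no transgene. Set B held the piRNA sensor in N2, the control sensor in N2 and the piRNA sensor in prg-1. Set C held the piRNA sensor in N2 and in mut-7. The number of placed reads was 6215726 for N2 and 6804342 for prg-1 in set A. It was 12010723, 13404960 and 9746281 in set B, in the order given above, and 9251961 and 5882484 in set C. Reads with a single placement made up between 88.97% and 95.2% of each library. Within a set every genotype other than N2 was seen in 1 library, so only the prg-1 comparison over sets A and B has any replication.

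The first comparison asks whether a site complementary to a piRNA is enough to bring 22G-RNAs onto a transgene, and whether this needs prg-1. The sensor encodes GFP fused to histone H2B. In the piRNA sensor, positions 1815 to 1835 of its contig are complementary to the piRNA 21UR-1 and lie after the H2B stop codon, within the 3′ untranslated region. Reads of 21UR-1 itself were not analysed here. In the control sensor, positions 1819 to 1831 match the last 13 bases of 21UR-1 in the piRNA's own direction. In N2 of set B, antisense 22G-class reads on the reporter (GFP to the end of the 3′ untranslated region) came to 176 RPM, reads scaled to a library size of 1000000 (95% interval 169 to 184, 2104 reads) with the piRNA sensor. With the control sensor they came to 15.8 RPM (13.7 to 18.0, 210 reads). The ratio was 11.2 (9.71 to 12.96). In prg-1 the piRNA sensor had 15.2 RPM (12.8 to 17.9, 142 reads), 11.62-fold less than in N2 (9.80 to 13.9). With reads placed on the sensor alone, these ratios were 15.6 and 28.7. They were 6.73 and 5.27 with reads of any length, and 5.13 (3.20 to 8.53) and 3.38 (1.79 to 7.03) with distinct sequences in place of reads. The difference between N2 and prg-1 was 22.2-fold (16.2 to 31.3) over GFP and 10.8-fold (8.41 to 14.1) over the site and 3′ untranslated region. Over H2B it was 1.39-fold with an interval that includes 1 (0.903 to 2.17). Part of the reads on H2B and on the 3′ untranslated region also have genomic placements. With reads placed on the sensor alone, the difference was 9.41-fold over H2B (2.97 to 47.8, on 36 and 3 reads) and 60.6-fold over the site and 3′ untranslated region (32.8 to 127, on 773 and 10 reads). With distinct sequences the difference was 3.07-fold over GFP (1.52 to 7.04), and with reads of any length it was 2.88-fold over the site and 3′ untranslated region (2.57 to 3.23). Sense 22G-class reads on the reporter rounded to 1 read or fewer in every sensor library. These intervals cover counting error only, and each condition was a single library.

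The same transgene carries a selection marker that encodes UNC-119, a protein required for normal movement. The 21UR-1 site lies outside the marker, which was not searched for sites of other piRNAs. Antisense 22G-class reads on the marker were at 121 RPM (115 to 127) with the piRNA sensor in N2 and 190 (183 to 198) with the control sensor. In prg-1 they were at 157 (149 to 165). The ratio of N2 to prg-1 on the marker was therefore 0.771 (0.716 to 0.829), against 11.62 on the reporter. Relative to miRNA reads it was 0.968, with an interval that includes 1 (0.900 to 1.04), and with distinct sequences in place of reads it was 0.409 (0.305 to 0.547).

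In set C, which asks whether the reads on the sensor need mut-7, antisense 22G-class reads on the reporter were at 669.7 RPM (653 to 687, 6150 reads) in N2 and 21.7 (18.0 to 25.9, 120 reads) in mut-7. That was a 30.9-fold difference (25.8 to 37.3). It was 14.5-fold with reads of any length and 2.14-fold (1.39 to 3.42) with distinct sequences. The UNC-119 marker was at 267 RPM (257 to 278) in N2 and 7.05 (5.01 to 9.64) in mut-7, a 37.9-fold difference (27.6 to 53.4), or 5.57-fold (2.76 to 13.1) with distinct sequences. Scaled to the marker, the reporter ratio of N2 to mut-7 was 0.815, on the other side of 1. The sense strand of rDNA took 4.79% of reads in mut-7 and 0.306% in N2 of the same set. The piRNA sensor in N2 itself differed 3.80-fold between sets C and B on the reporter (3.61 to 3.99) and 2.21-fold on the marker (2.07 to 2.36), so levels were compared only within sets.

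**Figure D1:**
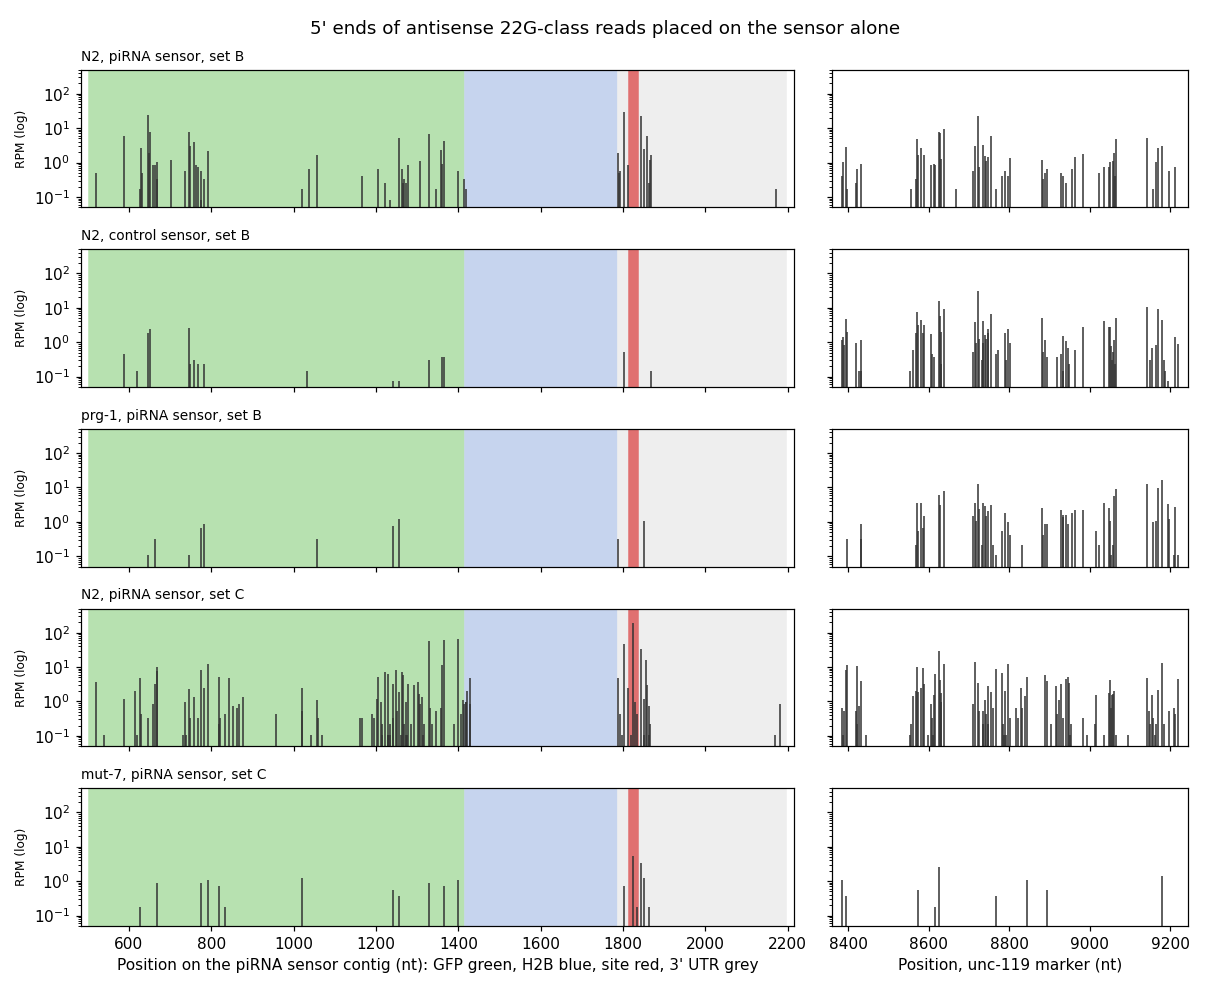
5′ ends of antisense 22G-class reads placed on the sensor alone, in RPM on a log axis, along the reporter (left) and the UNC-119 marker (right), 1 library per row. Reads placed on the sensor alone cluster in GFP and around the site in N2 with the piRNA sensor, while prg-1 keeps reads on the marker and mut-7 has few on either. Reads of H2B and of the 3′ untranslated region that also have genomic placements are left out, so gaps there need not mean an absence of reads.

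Antisense 5′ ends lay in GFP and on either side of the site. Of 1942 antisense 22G-class reads placed on the reporter alone in N2 of set B, 1133 lay in GFP, and in N2 of set C 3219 of 6053 did. With the piRNA sensor in N2 of set B, 407 reads (34.1 RPM) started within 100 nt before the site and 400 (33.5 RPM) within 100 nt after it. The control sensor had 7 and 2 reads there, and prg-1 had 3 and 10. In N2 of set C, 513 and 501 reads started in these intervals, and 1757 reads (191 RPM) started inside the site, where set B had 0. In mut-7 the 3 values were 4, 27 and 31 reads. Another 183 reads in N2 of set B and 1814 in N2 of set C started from -500 to -400 nt, counted from the site. No uniquely placed read started from 100 to 300 nt before the site or from 100 to 300 nt after it in any library, and reads shared with genomic sequence are not counted there.

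21U reads, the class bound by the Piwi protein PRG-1, were nearly lost in both prg-1 libraries. In set A they made up 0.699% of reads in N2 (0.692 to 0.705) and 0.00944% in prg-1 (0.00872 to 0.0102). In set B they made up 1.40% with the piRNA sensor and 1.19% with the control sensor in N2, and 0.0156% in prg-1 (0.0149 to 0.0164). The log2 ratio of prg-1 to N2 was -6.21 in set A and -6.37 in set B, where both N2 libraries had a log2 SD of 0.17. With distinct sequences in place of reads it was -2.56 and -1.66. In mut-7 the share was higher than in N2, at 3.08% against 0.822%, 3.74-fold by reads and 2.30-fold by distinct sequences. The number of distinct 21U sequences was lower there, at 4284 against 6910, among fewer distinct sequences in all. Of 1257 sequences tested with limma, 815 fell at an adjusted p under 0.05. None rose, with 0 that rose at an unadjusted p under 0.05 as well, and 1042 (82.9%) had no read in either prg-1 library. The prg-1 libraries held only 642 and 1523 21U reads, so the filter chose sequences largely by their level in N2. The lack of rises and the share without prg-1 reads partly reflect this choice. The 5 sequences with most reads in N2 all lie on chromosome IV. They start at 15351425 on the plus strand and at 16568390, 16209722, 15898269 and 5823223 on the minus strand. The first, TTGAACTGGTCGCTGTGATGG, had 6303 reads in the 3 N2 libraries of sets A and B and 5 in both prg-1 libraries together (log2 fold change -6.35, SE 0.67, limma adjusted p = 9.45e-18). The others had between 4442 and 5180 N2 reads and between 0 and 6 prg-1 reads. All 5 had the same SE, because the fit pooled the spread over sequences. Their p-values therefore do not measure the spread of a single sequence between libraries. The first had log2 changes of -5.05 in set A and -7.33 in set B. The number that fell was 280 without the piRNA sensor library of N2, where 626 sequences were tested, and 46 of 8186 with no filter on low values.

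The 22G class made up less of the library in each mutant. In set A it took 22.6% of reads in N2 and 18.6% in prg-1. In set B it took 18.0% and 22.6% in N2 with the piRNA and control sensors, and 8.98% in prg-1. In set C it took 35.9% in N2 and 13.04% in mut-7. The log2 ratios to N2 were -0.28, -1.17 and -1.46, and the log2 SD of both N2 libraries of set B was 0.23, so the difference in set A is close to that spread. As a share of distinct sequences the class was lower by much less, with log2 ratios of -0.16, -0.22 and -0.28. The total of distinct sequences, of which this class is a large part, was lower too. Distinct 22G-class sequences numbered 332895 in N2 and 219107 in prg-1 of set A. They numbered 210757 and 306408 in N2 and 82619 in prg-1 of set B, and 600024 in N2 and 133385 in mut-7. The share of the 26G class moved the other way. The class was set by length and first base alone, and can include primary small RNAs made with the Argonautes ERGO-1 and ALG-3/4. Its share was 2.82-fold higher in prg-1 of set A, 2.07-fold higher in prg-1 of set B and 2.57-fold higher in mut-7. Reads of 26 nt starting with A, C and T were at 0.172%, 0.157% and 0.233% in mut-7, against 0.0485%, 0.0294% and 0.0638% in N2. In prg-1 of set B they were at 0.419%, 0.0426% and 0.314%, against at most 0.0748%, 0.0250% and 0.119% in N2. In set A they were at 0.382%, 0.0317% and 0.0478% in prg-1, against 0.364%, 0.0140% and 0.0390% in N2. In sets B and C the rise was thus not particular to reads that start with G. miRNAs took 59.3% of reads in N2 and 65.9% in prg-1 of set A, 58.8% and 51.9% in N2 and 71.4% in prg-1 of set B, and 34.2% in N2 and 47.1% in mut-7. Mitochondrial reads were at 3.75% in prg-1 of set B, against 0.492% and 0.464% in N2 of that set, and at 1.19% in mut-7, against 0.425% in N2. Sense rDNA reads, at 4.79% in mut-7, were at 1.35% in prg-1 of set A, against 0.432% in N2, and at 0.276% in prg-1 of set B, against 0.189% and 0.137%.

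**Figure D2:**
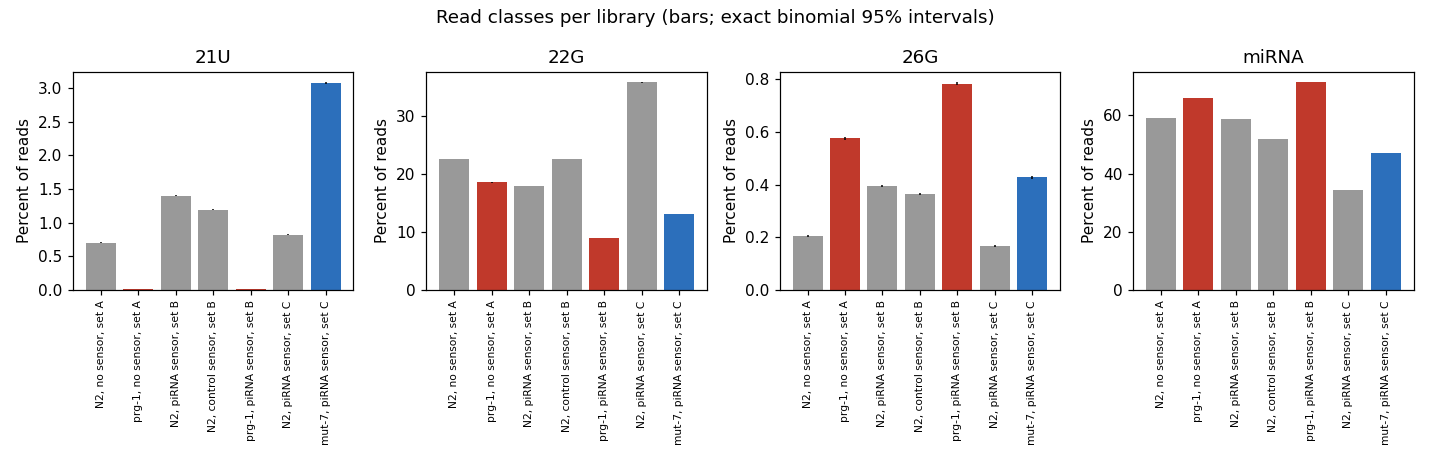
Share of reads in the 21U, 22G, 26G and miRNA classes for each library, in percent of placed reads, with exact binomial 95% intervals that are mostly too small to see. N2 is grey, prg-1 red and mut-7 blue. 21U stands at 0.00944% and 0.0156% in the prg-1 libraries and at 3.08% in mut-7.

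Across the genome, 4330 of 19457 windows lost 22G-class reads in prg-1 and 438 gained them (limma, adjusted p under 0.05). Of these, 4327 and 437 moved the same way in both sets. This agreement is largely built into the fit, where a difference between the sets adds to the residual spread. Over all 19457 windows the log2 ratios of sets A and B had a Pearson's r of 0.643. Adjacent windows are not independent, and the calls formed 2741 runs that fell and 308 that rose. Over all windows tested the median log2 change was -0.79. With libraries scaled by the median of ratios, an alternative chosen after the data were seen, it was -0.16. The split was then 3679 fell and 1758 rose, so that 32.3% of calls rose in place of 9.19%. The number that fell was 1813 without the piRNA sensor and 2353 without the control sensor library of N2, and 9794 and 10086 without N2 or prg-1 of set A, when only set B informs on genotype. The number that rose was 109 and 221 without those sensor libraries of N2, and 846 without prg-1 of set B. With distinct sequences 46196 windows were tested, and 2959 fell and 246 rose. With no filter on low values 95034 windows were tested, and 57 fell and 1 rose.

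Several windows lost nearly all their reads. The window at 14143001 to 14144000 on the plus strand of chromosome II fell from 625 to 0.294 RPM in set A. In set B it fell from 505 and 644 to 1.20 (log2 fold change -8.41, SE 0.50, limma adjusted p = 1.08e-05). The window at 9104001 to 9105000 on the plus strand of chromosome IV fell from 400.4 to 0.147 in set A and from 287 and 376 to 0.308 in set B (log2 fold change -8.18, SE 0.49). The window at 13397001 to 13398000 on the minus strand of chromosome X had the highest mean of the group and fell from 464 to 2.79 in set A and from 776 and 1010.4 to 2.62 in set B (log2 fold change -7.51). The other 9 had log2 changes between -7.78 and -7.31. Of these, 6 were on chromosome I, with the minus strand at 11060001, 11061001 and 3373001 and the plus strand at 248001, 11069001 and 10784001. Another 2 neighboured each other on the minus strand of chromosome II, at 13123001 and 13124001, and 1 was at 8794001 on the minus strand of chromosome III. What these windows contain was not analysed here.

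The 10 named windows that rose had at most 17.2 RPM in any N2 library of sets A and B. The window at 14718001 to 14719000 on the minus strand of chromosome I rose from 2.41 to 141 RPM in set A and from 0.583 and 0.522 to 102 in set B (log2 fold change 5.76, SE 0.49, limma adjusted p = 1.77e-05). The window at 10934001 on the plus strand of chromosome II rose from 17.2 to 606 in set A and from 1.91 and 2.24 to 99.8 in set B (log2 fold change 5.05). The other 8 had log2 changes between 4.96 and 5.52. They start at 5517001 (chromosome II, plus), 14444001 and 14445001 (V, minus), 7485001, 7562001, 8210001 and 8211001 (IV, plus) and 12504001 (I, minus).

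**Figure D3:**
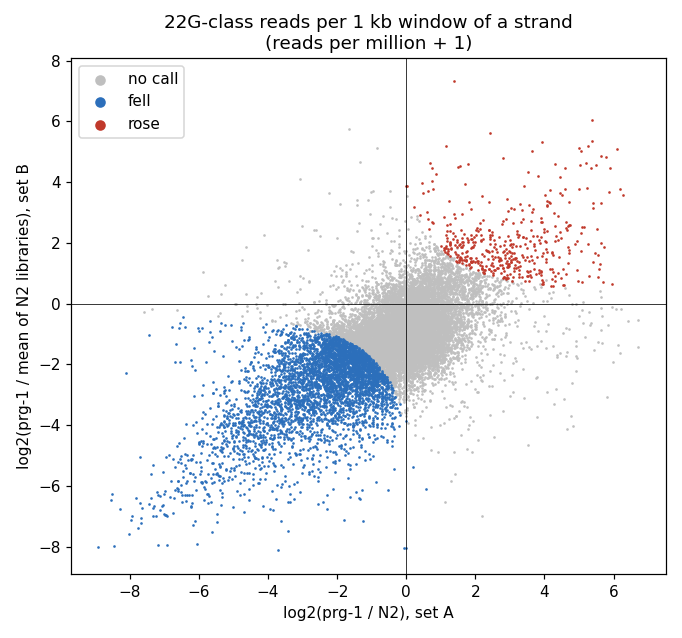
Log2 ratio of prg-1 to N2 for 22G-class reads (RPM plus 1) in 19457 windows of 1 kb, set A on the horizontal and set B on the vertical axis. Windows that fell (4330, blue) or rose (438, red) at an adjusted p under 0.05 lie almost all in the quadrants where both sets have the same sign. The fit favours this, because a difference between the sets adds to the residual spread.

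Reads were also summed over DNA transposons of the Tc1/mariner superfamily. On Tc3, 22G-class reads were lower in all mutant libraries, at 416 against 727 RPM in set A and 54.3 against 395 and 494 in set B. Of 71 windows that overlap a Tc3 element, 21 (29.6%) fell and 0 rose by limma's adjusted p, with 33 and 1 at an unadjusted p under 0.05. Outside Tc1, Tc3, rDNA and the 2 parts of chromosome IV used for 21U, 22.3% of windows fell. On Tc1 the sets pointed in opposite directions, with 2187 RPM in prg-1 against 842 in N2 of set A, and 546 against 606 and 773 in set B. Of 97 windows that overlap a Tc1 element, 11 (11.3%) fell and 3 rose. In mut-7, Tc1 was at 167 RPM against 1912 in N2 and Tc3 at 343 against 992. With distinct sequences the ratios to N2 in sets A, B and C were 0.899, 0.639 and 0.584 for Tc3, in place of 0.573, 0.123 and 0.345. For Tc1 they were 1.27, 1.97 and 0.505, in place of 2.598, 0.797 and 0.0873, so that the ratio of set B changed direction. These are shares of all distinct sequences in a library, whose total was lower in each mutant library. Counted as such, distinct 22G-class sequences of Tc1 were fewer in prg-1. They numbered 485 against 521 in N2 of set A, and 287 against 343 and 434 in set B. Reads of either family have many placements and do not tell the copies apart.

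**Figure D4:**
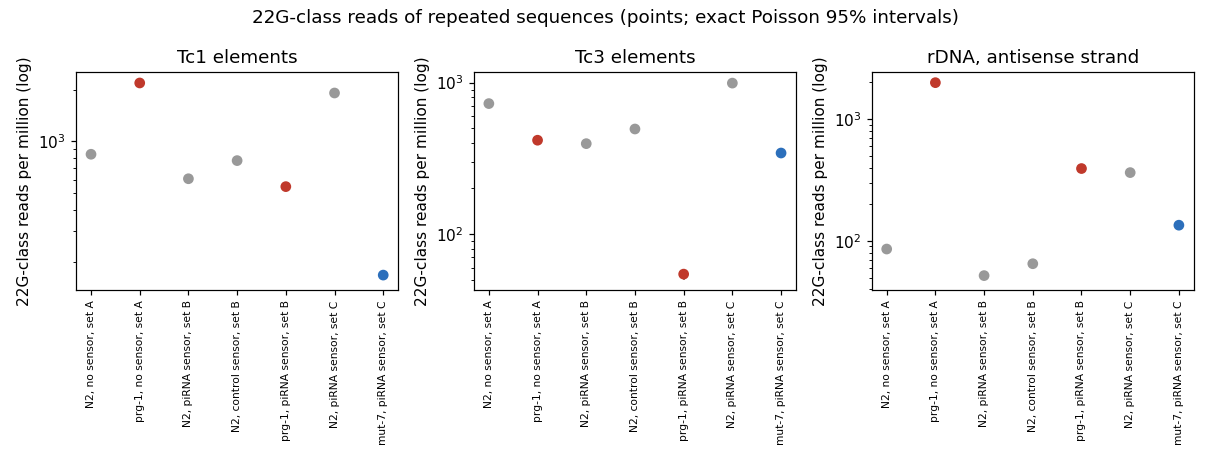
22G-class RPM (log axes) on Tc1 elements, Tc3 elements and the antisense strand of rDNA in each library, with exact Poisson 95% intervals that are smaller than the points. N2 is grey, prg-1 red and mut-7 blue. Tc1 has its lowest value in mut-7 (167) and Tc3 in prg-1 of set B (54.3).

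miRNAs, which do not depend on the piRNA pathway, gave 1 call among 87 tested and 8 at an unadjusted p under 0.05. mir-235 was higher in prg-1 in both sets, at 3619 against 431 RPM in set A and 956 against 127 and 123 in set B (log2 fold change 2.99, SE 0.35, limma adjusted p = 0.046). The call was lost relative to miRNA reads (limma adjusted p = 0.068), without the set term (0.998), and without the piRNA sensor (0.180) or the control sensor (0.800) library of N2. The log2 fold change stayed between 2.71 and 3.29. Over all alternatives the adjusted p ran from 1.17e-11 to 0.998. Next by p were mir-83 (log2 fold change 1.64), mir-61 (-1.85), mir-248 (1.96) and mir-38 (-1.42), none past the threshold. The miRNAs with most reads summed over the 7 libraries, mir-58, mir-80, mir-1, let-7 and mir-48, had log2 changes of 0.08, 0.67, -0.09, 0.23 and -0.62. Their levels in N2 differed between sets. For let-7 they were 9442 RPM in set A, 78121 and 62744 in set B, and 34.2 in set C. The mir-35 family, which is abundant in embryos and oocytes, had a median log2 change of 0.84 in set A and -1.42 in set B. None of its 8 members passed, also none adjusted over the list alone. Camera put it lower (adjusted p = 0.036), with adjusted p = 0.95 with an estimated correlation, and fry gave an adjusted p of 0.98. Within the family, mir-40 and mir-35, the members with most reads, had log2 changes of -0.08 and -0.99, and mir-38 one of -1.42. mir-40 was at -1.47 in set B alone and 1.77 in set A alone. The let-7 family, which times larval development, had medians of -0.65 and 0.62 in sets A and B and camera adjusted p = 0.97. Its member mir-794 had a log2 change of 1.10 with a limma adjusted p of 0.45. The tissue-restricted miRNAs mir-1, lsy-6 and mir-124 had medians of -0.14 and 0.17 and the same camera adjusted p, with log2 changes of -0.09, 0.08 and 0.04. In both lists 0 members passed by limma, also adjusted over the list alone. Without the prg-1 library of set B, when only set A informs on genotype, 24 miRNAs fell and 21 rose, and without either library of set A 8 fell and 18 rose.

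In mut-7 the loss of 22G-class reads was broad. Of 8082 windows with at least 50 reads in the higher library, 4037 (49.95%) were at least 4-fold lower in mut-7 and 120 (1.48%) at least 4-fold higher, with a median ratio of 0.251. No replicate backs these ratios. The N2 library had more reads (9251961 against 5882484) and a larger 22G share, so windows passed the rule largely through N2. This choice favours lower ratios. Summed over the whole class, the ratio on this scale was 0.384. With the N2 sensor library of set B as control the numbers were 2924 and 947, and relative to miRNA reads 4512 and 38. With distinct sequences 774 of 1402 windows were lower and 0 higher. All 57 windows on Tc1 elements were at least 4-fold lower, and 11 of 32 on Tc3. Windows on different copies of a family share the same reads, so they are not separate results. The 12 lowest had 0 reads in mut-7. The first of them, at 16313001 on the minus strand of chromosome IV, had 2626 reads in N2 and was at least 527-fold lower, and those at 3770001 (X, plus), 85001 (I, plus) and 1086001 (III, minus) were at least 491-fold, 428-fold and 395-fold lower. The remaining 8 were at least 195-fold to 311-fold lower. They start at 2057001, 11053001, 13265001 and 2055001 on the plus strand of chromosome I, 5415001 on the minus strand of X, and 20511001 (V), 12857001 (III) and 4132001 (IV) on the plus strand. Of the 8 highest ratios, 6 lay on the sense strand of rDNA, led by 15065001 at 19.7-fold (17.3 to 22.6). The others were at 2452001 on the plus strand of chromosome II, 16.6-fold higher (12.1 to 23.2), and 13464001 on the plus strand of chromosome I, 4.86-fold higher (3.95 to 6.01).

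Windows that fell in prg-1 were more often lower in mut-7 than others. Of 7773 windows in both comparisons, 3032 fell in prg-1 and 3921 were at least 4-fold lower in mut-7, and 2139 did both, 1.40 times the 1529 expected by chance (exact hypergeometric p = 8.14e-181). The comparisons share no library. Among the windows that fell, 70.5% were lower in mut-7, against 37.6% of the others. These others include 160 windows that rose in prg-1, of which 133 (83.1%) were lower in mut-7, so the overlap was not particular to windows that fell. Of the 438 windows that rose, only these had enough reads in set C, largely in N2, which favours lower ratios. Of the 4581 with no call, 1649 were lower. Because neighbouring windows are not independent, this p is too small.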

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

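All tests in this part were chosen after results in these libraries had been seen. The grouping by first bases was set down before its p was computed, but from single miRNA ratios already seen.

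Reads outside the main comparisons stood above N2 of the same set in these libraries. Mitochondrial reads were 3.75% in prg-1 of set B, against at most 0.492% in N2 of its set, and 1.19% in mut-7, against 0.425%. In prg-1 of set A they were below N2, at 0.265% against 0.362%, but 2.22-fold above it by distinct sequences. Sense rDNA reads were 1.35% in prg-1 of set A, against 0.432% in N2, 0.276% in prg-1 of set B, against at most 0.189%, and 4.79% in mut-7, against 0.306%. These sense ratios were 3.13, 1.71 and 15.7 by reads, and 2.50, 2.54 and 4.33 by distinct sequences.

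22G-class reads antisense to rDNA stood at 0.199% in prg-1 of set A and 0.0393% in prg-1 of set B, above at most 0.00858% and 0.0065% in N2 of the same sets, rises of 23.2-fold and 6.76-fold, or of 5.15-fold and 5.96-fold with distinct sequences in place of reads. Of 23 windows in the region, on both strands, 11 rose and 0 fell by limma's adjusted p, with 14 and 0 at an unadjusted p under 0.05. Fragments of rRNA come from the sense strand and would raise sense reads at least as much. In sets A and B the antisense rise was 7.41 and 3.94 times the sense rise by reads. By distinct sequences it was 2.06 (1.79 to 2.37) and 2.34 (1.94 to 2.83) times. The N2 libraries of set B differed 1.73-fold and 1.53-fold in this quotient. Against that spread alone, the values argue against fragments as the whole cause. Between N2 of sets A and C the quotient differed more, at 85.8 antisense and 4322 sense RPM against 364 and 3062. By distinct sequences the numbers were 261 and 9037 against 517 and 7126. This spread is wider than the quotients of set B, so whether fragments are the whole cause is not settled. Unequal ligation to 5′ barcodes is absent from set B, where the rise was 6.68-fold (6.29 to 7.09) over the pooled N2 libraries. The N2 libraries spread 7.01-fold by reads and 2.04-fold by distinct sequences over the 3 sets, where protocols differ too, and 1.25-fold and 1.07-fold within set B, and as the labels do not say which libraries are separate cultures, differences between cultures cannot be told apart from an effect of prg-1.

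Across 87 miRNAs, which are not independent, the log2 ratios of prg-1 to N2 in sets A and B had a Pearson's r of 0.0155, which argues against an effect of prg-1 as the source of the ratios of set A as a whole. Single miRNAs did move alike, with log2 ratios of 3.07 and 2.93 for mir-235, 1.79 and 1.53 for mir-83, and -2.52 and -1.36 for mir-61. The libraries of set A had different 5′ barcodes, and miRNAs that start with the same 3 bases shifted together there (78 miRNAs in 17 groups, 45.5% of variance between groups, permutation p = 0.00217), as unequal ligation would predict. The same test gave a permutation p of 0.0418 in set B, which has no 5′ barcodes, so the test does not single out ligation, which cannot be told apart from families that change together. Without the let-7 and mir-35 families, looked at in addition (63 miRNAs in 17 groups), the permutation p was 0.00692 in set A and 0.872 in set B.

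The 22G share was lower in every mutant library than in N2 of its set. The log2 ratios in sets A, B and C were -0.28, -1.17 and -1.46 by reads. They were only -0.16, -0.22 and -0.28 by distinct sequences, whose total was also lower in each mutant library. Leaving out rRNA and mitochondrial fragments took away at most 5.38% of the log2 fall by reads in any set, which argues against dilution by them there, but 22.7%, 37.8% and 12.6% of the smaller falls by distinct sequences, where dilution as a cause cannot be told apart from a loss of 22G-RNAs. In set A the fall by reads is close to the log2 SD of the N2 libraries of set B (0.23). In mut-7, germline 21U reads were 3.74-fold above N2, or 2.72-fold relative to miRNA reads. This argues against less germline tissue there only if 21U levels within the germline do not depend on mut-7, which was not tested. N2 libraries spread at most 2.04-fold by reads on either scale. The share of distinct sequences, 2.30-fold above N2, cannot decide this, since the total of distinct sequences was lower in mut-7. Distinct 21U sequences themselves numbered 4284 in mut-7 and 6910 in N2. For embryo tissue 21U reads are no gauge. The summed reads of the mir-35 family in mut-7 were at 1.22 of their N2 level, in a single library. In prg-1, where 21U cannot serve, less germline or embryo tissue cannot be told apart from a loss of 22G-RNAs. The summed reads of the mir-35 family were at 0.374 of their N2 level in set B but 0.792 in set A, where 5′ barcodes differ. The sum in set A was carried by mir-42, at 1673 RPM in N2 and 283 in prg-1, while the members had a median log2 change of 0.84 there. An effect of the mutated genes stays open.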

How the results depend on the processing

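No pairing by replicate number was possible because the groups compared share fewer than 2 replicate numbers in the labels. The set letter was a term of the fit instead. Count models and trimmed-mean scaling were not run, since the files hold no table of counts, and all deposited reads became the main library size. The other scaling, pseudocount, duplicate and trend alternatives named here as added (median of ratios, pseudocounts, distinct sequences, variance trend, the marker as scale, and miRNA reads for miRNAs) were chosen after seeing the data. Where a value moved and its construction does not show why, the cause was not tested.

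The piRNA sensor over the control sensor gave a reporter ratio of 15.5 at exactly 22 nt, 6.73 at any length, 15.6 with reads on the sensor alone, 5.13 with distinct sequences and 17.7 relative to the marker. N2 over prg-1 gave 15.2, 5.27, 28.7, 3.38 and 15.1 in that order, and 14.6 relative to miRNA reads. N2 over mut-7 gave 44.8 relative to miRNA reads, 14.5 at any length, 2.14 with distinct sequences and 0.815 relative to the marker, which was itself lower in mut-7. With distinct sequences the marker ratio was 1.002 for piRNA over control sensor, 0.409 for N2 over prg-1 and 5.57 for N2 over mut-7.

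The windows that fell in prg-1 numbered 57 with no filter (95034 tested), 9704 with each placement in full, 7358 at any length and 5′ base, and 2331 with a pseudocount of 5. Those that rose numbered 1 with no filter, 220 and 235 without the set term in 5 and 6 libraries, 1152 with each placement in full, 712 at any length and 5′ base, 1758 with median-of-ratios scaling, 229 with a pseudocount of 5 and 246 with distinct sequences. Leaving out 1 library gave 1813 to 10086 that fell and 109 to 846 that rose. Where a genotype is then seen once in a set, that library is assumed to vary like the others, with 1 residual degree of freedom. For 21U, 46 fell with no filter and 218 with a pseudocount of 5, and leaving out 1 library gave 280 to 1173. For miRNAs, 0 rose without the set term and 0 relative to miRNA reads, and leaving out 1 library gave 0 to 24 that fell and 0 to 21 that rose, the highest of both without prg-1 of set B, when set A decides. For mir-40, leaving out 1 library gave log2 changes of -1.47 to 1.77 in place of -0.08.

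In mut-7, windows at least 4-fold higher numbered 38 relative to miRNA reads, 947 with N2 of set B, and 0 with distinct sequences, by which 774 of 1402 were lower. At 2-fold, 712 were higher. The named windows of prg-1 kept their direction in all 396 alternative values and their side of the threshold in 368. The 28 others came with no filter or with distinct sequences. With distinct sequences the log2 ratios of the 22G share were -0.16, -0.22 and -0.28 in sets A, B and C, and those of the 21U share -2.56, -1.66 and 1.20. The miRNA share was then 3.32-fold above N2 in mut-7, although it held 333 distinct miRNA sequences there and 371 in N2, of 393680 and 1458065 in all, so such shares also move with the number of distinct sequences in a library. The shares of the 22G, 21U, 26G and miRNA classes and the overlap kept their directions, while Tc1 in set B did not with distinct sequences (0.797 by reads, 1.97). Depth limits the low windows and the sensor values of prg-1 and mut-7, which rest on 142 and 120 reads.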

Other observations

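The patterns below were noticed in the data and no test was made for them. Of the 160 windows that gained 22G-class reads in prg-1 and had enough reads in set C, 0 were at least 4-fold higher in mut-7. Over all 8082 windows of that comparison only 1.48% were, so the 0 says little. The median ratio of mut-7 to N2 in the 160 windows was 0.064. Windows entered largely through their reads in N2 of set C, which favours low ratios. The windows that fell had a median ratio of 0.086, and those with no call one of 0.598.

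The 26G share was above N2 in all mutant libraries, at 0.576% and 0.783% in prg-1 and 0.427% in mut-7, where N2 libraries lay between 0.166% and 0.394%. In prg-1 of set B and in mut-7, reads of 26 nt with other first bases were higher too. The number of distinct 21U sequences with reads was 4868 in N2 and 606 in prg-1 of set A, 3790 and 3922 in N2 and 462 in prg-1 of set B, and 6910 in N2 and 4284 in mut-7.

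Windows that fell in prg-1 took 42.3% of the 1629 windows on the X chromosome and 20.4% of the 17828 on autosomes, with median log2 changes of -1.35 and -0.75. Those that rose took 2.03% and 2.27%.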
